A study of Mus musculus with 8 samples.

How the data were processed

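Acetylated histone H3 (H3ac) was profiled by chromatin immunoprecipitation and sequencing in RAW 264.7 cells, a mouse macrophage-like line, per the labels. The labels name 2 treatments, Gel and CuNZ@Gel, with 2 immunoprecipitated libraries each, and 4 input libraries for which no file was used here. Per the labels' protocols, cells were exposed to extracts for 48 h and fixed in 1% formaldehyde for 10 min, and chromatin was sheared to 150 to 350 bp. The one treatment protocol that all samples share speaks of CuNZ@Gel extracts only, so the handling of the Gel cells is taken from their treatment label. Nothing in the labels says that the 2 libraries of a group came from separate cultures, so the spread between them may be technical.

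The deposited files are 4 peak lists, 1 per library, and 2 group lists. Per the submitters' processing notes, fastp, SAMtools 1.17, MACS2 2.2.8 and deepTools 3.5.6 were used, on mouse build GRCm39. The aligner and the peak calling options are not given in the sources used here. The deposited lists give for each peak its start and end, a score, a fold enrichment over background, a −log10 p and a −log10 q. The score in the deposited lists equals the −log10 q multiplied by 10 and cut to a whole number for between 99.9856% and 99.995% of the peaks of a list. The −log10 q values of the deposited lists correspond to a q-value threshold of 0.05. The fold enrichment ratio and the score are the authors' own values per peak and were used to describe, rank or filter peaks within a list. Each deposited group list equals, in 100% of its entries, the intersection of the replicate 1 peaks with the replicate 2 peaks and carries the replicate 1 values (bedtools 2.31.1). Peaks were thus called per library, and the group lists are not an independent call on pooled samples.

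The files hold no read totals. A caller of this kind computes the fold as the summit fragments plus 1 divided by the background plus 1, and the p from a Poisson tail. Both equations were solved for a whole number of summit fragments and a background, which succeeded for 100% of the peaks in each list at a relative tolerance of 0.0001. On 5000 simulated peaks the solution returned the simulated fragments in 100% of cases. The commonest background of a list, in fragments per base, served as a measure of depth: 4.62 and 4.28 in Gel replicates 1 and 2, and 3.45 and 2.46 in CuNZ@Gel replicates 1 and 2. It scales with fragment number and fragment length together. Summit height below means summit fragments divided by this library background.

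Peaks on the 19 autosomes and on X and Y were merged across the 4 lists wherever they overlapped by at least 1 bp. A merged region counted as Gel-only with peaks in both Gel libraries and neither CuNZ@Gel library, and as CuNZ-only in the opposite case. These counts were set beside those of the other 2 ways to split 4 libraries into pairs. Peak number and covered length were compared by an exact two-sided permutation test over 6 assignments. Similarity of libraries was measured by the Jaccard index in bases. Coordinates are 1-based on GRCm39.

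The gene table given for this work is of another build (GRCm38) and the peak lists name no genes. Coordinates were not converted. The results planned per gene were therefore left out: promoter peaks, promoter covered width, 24 gene lists, regions near list genes, position classes and 24 named genes. The planned rule for naming items was carried over to regions: the 10 Gel-only and the 10 CuNZ-only regions with the largest difference of mean covered width. Regions with peaks in all 4 libraries, and regions picked by summit height, are named by rules chosen after their values were seen.

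The planned covered-width test needed a new unit. Bins of 4 kb were chosen before any fit was run, and bases covered by peaks were compared with limma 3.58.1 (trend and robust, R 4.3.3), with Benjamini-Hochberg adjustment at 0.05. Bins covered in no library, or alike in all 4, were left out. This test gave 0 calls. Regions in at least 2 libraries and regions in all 4 libraries were then tried as units, with those call counts in view, and the latter stood as the main unit for a time before the bins were put back. In all, 5 units were tried (bins of 4, 2 and 10 kb and both kinds of region), besides log2 widths and a fit of log2 summit heights. All of these are reported in the closing section, and no call from them is used as a main result. In simulated data for the bins, with variances drawn from the fitted prior, the estimated change was 994 bp for a true change of 1000 bp in 200 changed bins of 68188. None of those 200 was called at 500, 1000 or 2000 bp. With 13638 bins changed, 31.5% were called at 500 bp, 81.1% at 1000 bp and 96.5% at 2000 bp, with 356 false calls. The test can therefore miss sparse changes of any of these sizes. The simulated shifts went in both directions and were at least 500 bp, while the median difference over the real bins was -193 bp, CuNZ@Gel minus Gel. Power for a broad shift of that size in one direction was not simulated.

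Alternatives fixed before the data were examined were a stricter threshold (score at or above the list's median), lists cut to equal length, an overlap of 50% of the shorter peak, leaving out each library, and for the width test a replicate block, quantile normalization, a mean width of at least 500 bp and limma without trend and robust. Chosen after seeing the data were peaks at equal depth, a limit of 1.5 on local over library background, and the other width units. For equal depth, summit fragments were thinned to the background of CuNZ@Gel replicate 2, the shallowest library, in 20 random draws, and kept where they passed the lowest −log10 p of its deposited list. Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3 were used.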

Results

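H3ac, the acetylated form of histone H3 found at active promoters and enhancers, was mapped in RAW 264.7 mouse macrophage-like cells exposed for 48 h to Gel or to CuNZ@Gel. The series concerns a sprayable nanozyme hydrogel for diabetic wounds, and the comparison asks how H3ac differs between the 2 treatments. Each treatment had 2 immunoprecipitated libraries. The background of the lists, used as a measure of depth, was 4.62 and 4.28 fragments in the Gel libraries and 3.45 and 2.46 in the CuNZ@Gel libraries, so the CuNZ@Gel libraries were shallower. All positions are on GRCm39. No gene is named, because the peak lists carry no gene names and no annotation of this build was used here.

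The CuNZ@Gel libraries had fewer and less extensive H3ac peaks than the Gel libraries. Gel replicates 1 and 2 had 58612 and 60483 peaks on chromosomes, and CuNZ@Gel replicates 1 and 2 had 40075 and 34693. The means were 59548 ± 1323 (SD, n = 2) for Gel and 37384 ± 3806 (SD, n = 2) for CuNZ@Gel, which is 62.8% of the Gel mean. Peaks covered 42.8 ± 0.618 Mb (SD, n = 2) in Gel and 24.2 ± 2.78 Mb (SD, n = 2) in CuNZ@Gel, or 56.6% of the Gel length. Both differences exceeded the spread between replicates. The exact two-sided permutation p was 0.333 for each, the smallest that 2 against 2 libraries can give. With all libraries thinned to one depth, a calculation added after seeing the data, the means were 46292 ± 1321 and 35485 ± 1121 (SD, n = 2), and 48.8% of the deposited gap remained. Thinning can only remove called peaks, and CuNZ@Gel replicate 2, which sets the depth, lost none. Its lowest −log10 p of 3.41 was applied to all lists, where the lowest in both Gel lists was 3.12. The share that remained is thus not the effect of depth alone taken out.

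**Figure D1:**
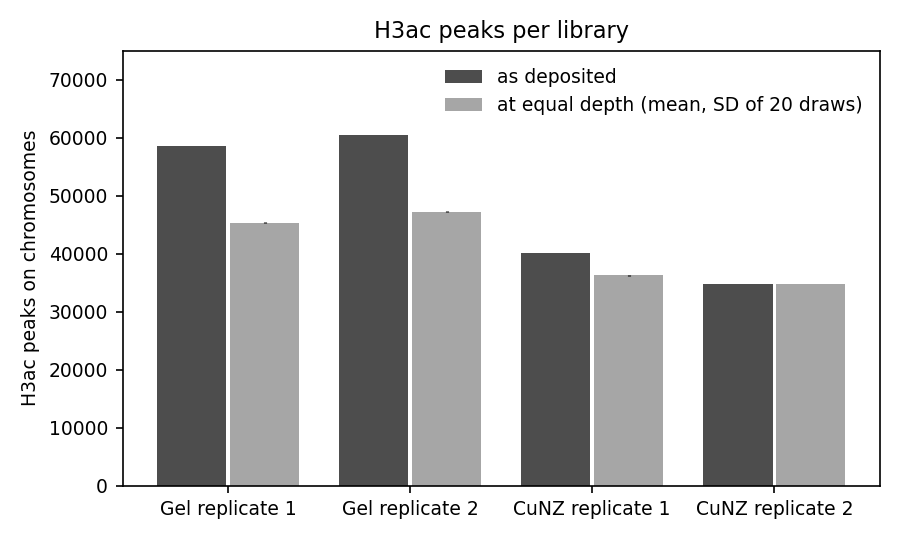
H3ac peaks on chromosomes (y axis) in each library, as deposited (dark bars) and after thinning to the depth of CuNZ@Gel replicate 2 (light bars, mean of 20 draws with their SD). Both Gel libraries have more peaks than both CuNZ@Gel libraries in either case, for example 45358 in Gel replicate 1 against 36278 in CuNZ@Gel replicate 1 at equal depth.

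Merging the 4 lists gave 81544 regions, of which 21909 had a peak in all 4 libraries. Gel-only regions numbered 9781 and CuNZ-only regions 259. Of the 39317 regions with peaks in both Gel libraries, 24.9% had no peak in either CuNZ@Gel library, 19.4% had one in a single CuNZ@Gel library and 55.7% had one in both. Of the 22791 regions with peaks in both CuNZ@Gel libraries, 96.1% also had peaks in both Gel libraries and 1.14% had none. The other 2 splits of the libraries, each pairing a Gel with a CuNZ@Gel library, gave between 664 and 1208 regions per pair. The Gel-only count lay above that range and the CuNZ-only count below it. Presence of a peak was not tested region by region. At equal depth the counts were 5531 Gel-only and 436 CuNZ-only, and with lists of equal length they were 2825 and 697, where the other splits gave 658 to 888.

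**Figure D2:**
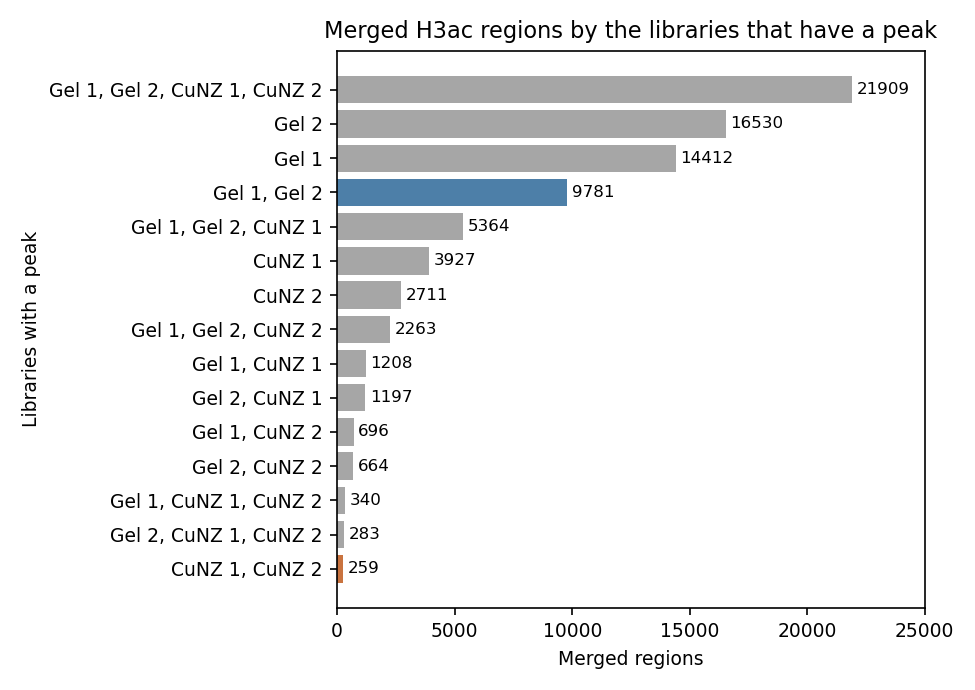
Number of merged H3ac regions (x axis) for each combination of libraries with a peak (y axis; CuNZ stands for CuNZ@Gel). Gel-only regions (blue) number 9781 and CuNZ-only regions (orange) 259.

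The Gel-only region with the largest difference of covered width lay on chromosome 8 from 108025053 to 108027614, with 2342 ± 38.9 bp under peaks in Gel (SD, n = 2) and none in CuNZ@Gel. It was followed by a region on chromosome 5 from 93412478 to 93414800, with 2119 ± 289 bp in Gel. A region on chromosome 13 from 30395807 to 30398116 had 2091 ± 310 bp, and one on chromosome 2 from 26327012 to 26329246 had 1949 ± 150 bp. On chromosome 15, from 78637924 to 78639712, 1758 ± 44.5 bp were covered in Gel. The other 5 of the 10 named Gel-only regions, on chromosomes 12, 2, 11, 14 and 13, had mean widths between 1540 and 1684 bp. Summit fragments of the 10 were 17 to 33 in the Gel libraries. None was checked singly at equal depth, so the lack of a CuNZ@Gel peak may reflect depth. The named CuNZ-only regions were smaller, but they are the extremes of 259 regions against 9781, and the CuNZ@Gel libraries were shallower. The largest lay on chromosome 19 from 9956121 to 9956945, with 752 ± 67.9 bp in CuNZ@Gel (SD, n = 2). The next was on chromosome 14 from 74971170 to 74972087, with 606 ± 252 bp, and the third on chromosome 7 from 16644116 to 16645028, with 605 ± 356 bp. A region on chromosome 3 from 87245562 to 87246159 had 558 ± 57.3 bp, and the other 6 named ones had 453 to 513 bp. The local background of that chromosome 3 region was 2.08 and 1.68 times the library background in CuNZ@Gel replicates 1 and 2. It was 3.23 times in both for another of the 10, on chromosome 8 from 21205509 to 21206105. Among the 10 named Gel-only regions, the local background was at most 1.56 times the library background. That value was in Gel replicate 1 for the first one named, on chromosome 8 from 108025053, with 1.26 times in Gel replicate 2. The median region width was 463 bp for Gel-only, 335 bp for CuNZ-only and 1225 bp for regions with peaks in all 4 libraries.

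Regions missing from the CuNZ@Gel lists were mostly weak in Gel. The regions with peaks in both Gel libraries were put into 10 groups of equal size by mean Gel summit height. In the weakest group, with a median height of 3.59 times background, 76.1% had no CuNZ@Gel peak. This share was 20.5% in group 5, 2.31% in group 7 and 0.025% in group 10, where the median height was 27.1. The 5 weaker groups held 96.0% of the Gel-only regions. The 2 strongest groups held 3 Gel-only regions among 7864. These 3, on chromosome 9 from 123724523 and on chromosome 8 from 20692811 and from 20697432, had high local background. It was 7.556 to 18.405 times the library background in the Gel libraries, and the authors' fold enrichment was only 1.444 to 2.475. Height over the library background thus overstates their strength. A gradient also arose with peaks of Gel libraries alone, although the depth, the p limit and the dilution used values of CuNZ@Gel replicate 2. The regions of Gel replicate 1 were put into 10 groups by strength. Gel replicate 2, thinned and diluted to the level of CuNZ@Gel replicate 2, called 8.44% of the weakest group and 99.7% of the strongest. CuNZ@Gel replicate 2 called 4.59% and 99.6%. Between these ends the shares lay further apart, for example 53.5% against 39.7% in group 6 and 75.6% against 61.0% in group 7.

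**Figure D3:**
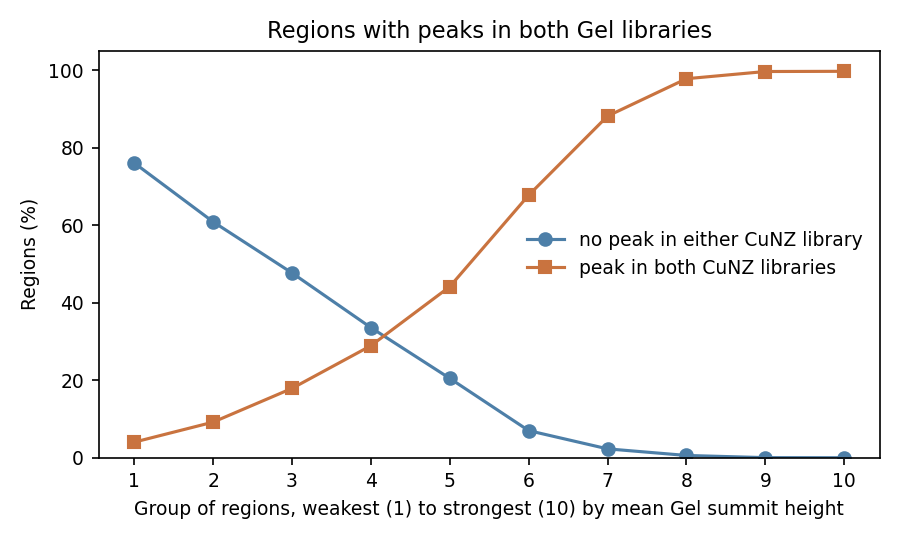
Share of the regions with peaks in both Gel libraries (y axis, %) that have no peak in either CuNZ@Gel library (circles) or a peak in both (squares), for 10 groups of regions from weakest (1) to strongest (10) by mean Gel summit height (x axis). The first share goes from 76.1% in group 1 to 0.025% in group 10.

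Where all 4 libraries had a peak, peaks covered less of the region in CuNZ@Gel. The median covered width was 1086 and 1087 bp in Gel replicates 1 and 2 and 788 and 692 bp in CuNZ@Gel replicates 1 and 2. Of the 21909 regions, 74.5% were narrower in both CuNZ@Gel libraries than in both Gel libraries and 1.26% were wider in both, where exchangeable libraries give 16.7% for each. The widths are not corrected for depth, and both CuNZ@Gel libraries were shallower, so this share is not a no-change value. The region with the largest difference lay on chromosome 15 from 8996619 to 9004197, with 7488 ± 45.3 bp in Gel and 1362 ± 9.9 bp in CuNZ@Gel (SD, n = 2). On chromosome 2, the region from 79085272 to 79095692 had 10361 ± 70.7 and 5814 ± 311 bp, and the region from 163479357 to 163486419 had 6607 ± 79.9 and 2626 ± 32.5 bp. On chromosome 4, from 53832612 to 53836361, the values were 3567 ± 259 and 250.0 ± 126 bp. The opposite order was seen on chromosome 6, where the region from 123237805 to 123242849 had 1634 ± 101 bp in Gel and 4890 ± 214 bp in CuNZ@Gel. On chromosome 10, from 51355962 to 51360983, the widths were 2216 ± 14.8 and 4274 ± 438 bp. On chromosome 3, from 50395192 to 50398292, they were 1098 ± 385 and 2633 ± 251 bp. These regions were picked as the extremes of all tested, by a rule chosen after the data were seen, so their differences are at the upper end of what chance and effect give together.

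**Figure D4:**
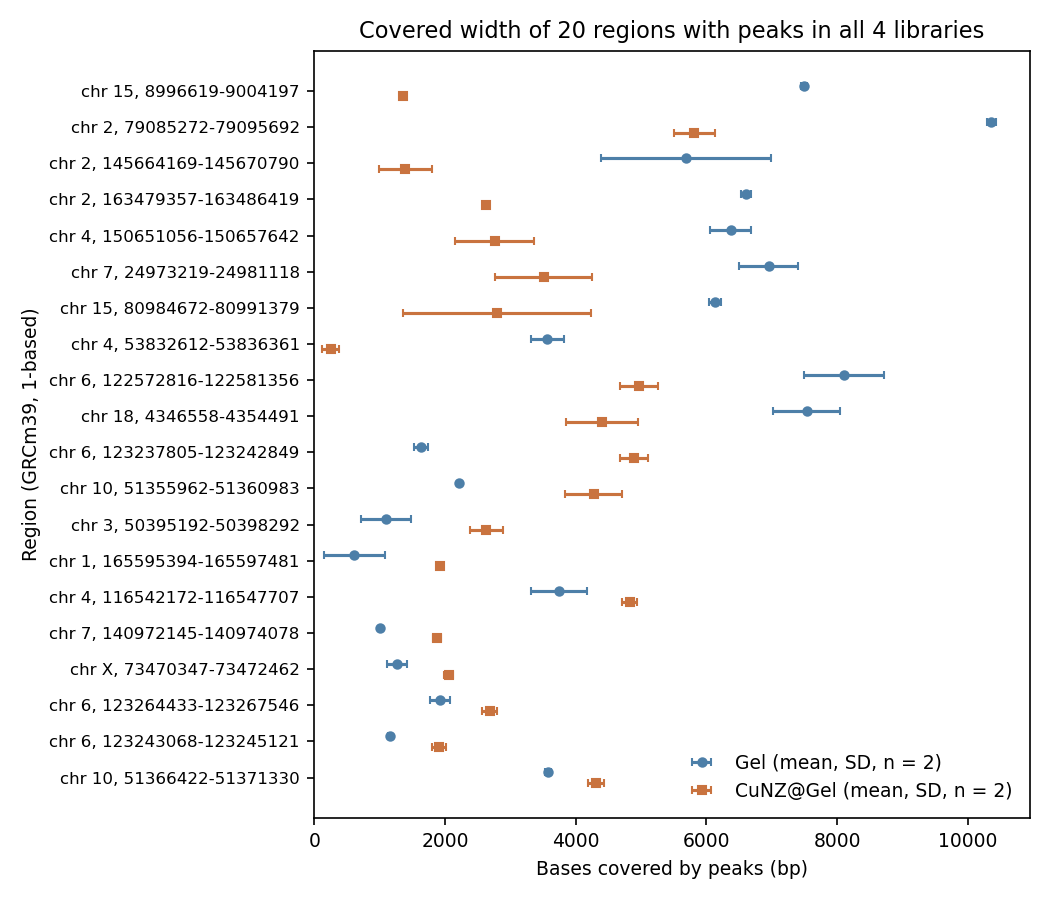
Bases covered by peaks (x axis, bp) in 20 regions with peaks in all 4 libraries (y axis, chromosome, start and end), 10 with the largest lower and 10 with the largest higher mean in CuNZ@Gel. Circles are Gel means and squares CuNZ@Gel means, with bars of 1 SD (n = 2); the region on chromosome 15 from 8996619 has 7488 bp in Gel and 1362 bp in CuNZ@Gel.

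Tested bin by bin, no difference of covered width passed the threshold. Of 68188 bins of 4 kb, limma called 0 lower and 0 higher in CuNZ@Gel at an adjusted p of 0.05. The smallest adjusted p from limma was 0.0697, and 16254 bins, or 23.84%, had an unadjusted p under 0.05. The other 2 splits of the libraries gave 89 and 98 such bins, also with 0 calls. Each side of those splits held a Gel and a CuNZ@Gel library, so the group difference entered their spread. That lowers their counts, which therefore give no level for the absence of change. With 23.84% of bins at an unadjusted limma p under 0.05, the lack of calls does not mean that covered width was alike in the groups. These widths are not corrected for depth, which also differed between the groups. With the replicate number as a block, 11123 bins were called lower. That fit assumes that same-numbered libraries pair, which is not known. It also leaves fewer residual degrees of freedom than the 2 of the main fit. The count of calls was not stable: settings that left out no library gave from 0 to 11123 bins or regions lower. Without Gel replicate 1 or 2 it was 21376 or 19580, but there the spread comes from the CuNZ@Gel pair alone and the lone Gel library is assumed to vary like it.

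The similarity of libraries within and across groups depended on the measure. The Jaccard index of covered bases was 0.622 between the Gel libraries and 0.607 between the CuNZ@Gel libraries, against 0.452 to 0.521 for the 4 pairs across groups. Unequal list lengths lower this index, but with lists of equal length the mean within groups was still 0.105 above that across groups, against 0.128 as deposited. The shared bases as a share of the smaller list had the opposite order, 0.775 and 0.822 within groups against 0.894 to 0.918 across groups, a measure that the longer Gel lists raise across groups. The deposited Gel group list had 43947 intervals on chromosomes covering 32.8 Mb, and the CuNZ@Gel group list had 28072 covering 18.3 Mb. Of the Gel intervals 51.6% overlapped a CuNZ@Gel interval, and of the CuNZ@Gel intervals 95.4% overlapped a Gel interval. Within the Gel group list, the authors' fold enrichment had a median of 8.19 for overlapping intervals and 3.74 for the others. Chromosome X had the lowest Gel-only share among the chromosomes with over 500 regions, 17.5% of 567, where the strength of its regions alone gave 15.9%. Chromosome 17 had the highest, 27.8% of 1820, against 25.7% from strength.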

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

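Peaks on unplaced scaffolds entered none of the comparisons and were looked at for this reason. Gel replicates 1 and 2 had 116 and 103 such peaks, and CuNZ@Gel replicates 1 and 2 had 89 and 78. No control sample sets a level for them, so they are given as values only. Groups of 2 libraries were too small for a test of single libraries standing apart.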

How the results depend on the processing

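The settings at equal depth, with a limit on local background, and all units of covered width including the 4 kb bins were chosen after the files were seen; the others were planned. Lower peak number, lower covered length, higher Jaccard index within groups and more Gel-only than CuNZ-only regions held in every setting run. Leaving out 1 library could not reverse the first 3, whose deposited values did not overlap. Peak number, CuNZ@Gel minus Gel, was -22164 as deposited and -10807 at equal depth. The stricter threshold cuts each list at its own median score, so its -11428 was not a test of direction. Covered length differed by -18.6 Mb, by -14.7 Mb at the stricter threshold and by -11.4 Mb with equal list length. The Jaccard index within minus between groups was 0.128, 0.177 at the stricter threshold, 0.105 with equal list length, and 0.107 to 0.165 without any 1 library. Gel-only regions numbered 6218 at the stricter threshold, 2825 with equal list length, 5531 at equal depth, and 12044 to 26311 without any 1 library. CuNZ-only regions numbered 41, 697 and 436 in the same 3 settings, and 542 to 4186 without any 1 library. A lone library counts its unshared peaks, which raises the counts without any 1 library. Leaving out a Gel library thus favours Gel-only regions. CuNZ-only regions lay below the range of the other splits as deposited, at the stricter threshold, with 50% overlap, with the background limit and at equal depth, but with equal list length 697 lay between 658 and 888. With 50% overlap, 50.9% of the Gel and 94.0% of the CuNZ@Gel group list overlapped the other.

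Covered-width calls were not stable. The 4 kb bins gave 0 lower and 0 higher (limma, 16254 with an unadjusted p under 0.05), as did 2 kb bins (18354), equal list length (10190), limma without trend and robust (19335) and regions in at least 2 libraries (19302). Lower and higher calls were 2383 and 3 with 10 kb bins, 3238 and 11 at the stricter threshold, 1630 and 232 with quantile normalization, and 4761 and 19 at a mean width of at least 500 bp. Without 1 library they ranged from 0 to 21376 lower and from 0 to 84 higher, with 0 when either CuNZ@Gel library was left out. In all such fits the spread comes from the other group's pair alone, and the lone library is assumed to vary like it. Regions in all 4 libraries, picked after the bins had given 0, gave 3923 and 13, and 1769 and 8 with log2 widths. Leaving out any 1 library then gave 0 calls. Whenever calls were made most were lower in CuNZ@Gel, but their number cannot be taken from any 1 setting, and the cause was not tested.

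With the replicate number as a replicate block, the bins gave 11123 lower and 32 higher. That fit left fewer residual degrees of freedom than the 2 of the main fit. The deviations of same-numbered libraries correlated at 0.0092 over bins, so the numbers are not known to pair the libraries. The alternatives planned for promoters, gene lists, distances to genes and position classes were not run, as no annotation of the build was used. Thinning to the depth of the shallowest library kept 77.4% and 78.1% of the peaks of Gel replicates 1 and 2.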

Other observations

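The tests of depth, of immunoprecipitation yield and of summit heights, the use of CuNZ@Gel replicate 1 in the dilution test, and the choice of the regions named by height, followed after the results were seen. The regions that were wider in CuNZ@Gel lay partly side by side. Of the 10 with the largest gain of covered width among regions with peaks in all 4 libraries, 3 lay on chromosome 6 between 123237805 and 123267546 and 2 on chromosome 10 between 51355962 and 51371330. Summit heights, in multiples of the library background, are given for Gel replicates 1 and 2 against CuNZ@Gel replicates 1 and 2 and come from separately called lists. On chromosome 6, they were 6.07 and 5.84 against 18.9 and 24.0 in the region from 123237805, 8.45 and 6.30 against 13.6 and 14.2 in that from 123243068, and 14.5 and 18.0 against 25.8 and 24.0 in that from 123264433. On chromosome 10, they were 14.1 and 13.5 against 26.7 and 32.6 in the region from 51355962, and 25.1 and 25.9 against 29.6 and 30.9 in that from 51366422. In fragments, before this scaling, the last was lower in CuNZ@Gel, with 116 and 111 against 102 and 76. The values overlapped between groups in the regions from 123243068, with 39 and 27 against 47 and 35, and from 123264433, with 67 and 77 against 89 and 59. In the opposite direction, the heights were 66.3 and 64.0 against 27.0 and 24.0 in the chromosome 2 region from 79085272, and 19.5 and 20.8 against 8.41 and 8.55 in the chromosome 15 region from 8996619.

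The lower number of peaks in CuNZ@Gel was weighed against 3 explanations. Lower depth as the whole cause is argued against by the lists at equal depth, where the smaller Gel list still held at least 1.247 times the peaks of the larger CuNZ@Gel list in each of 20 draws. Enrichment lower by one factor everywhere, beside the lower depth, was tested by thinning one Gel library and diluting it by the factor seen at the strongest regions, 0.738 to 0.756. Of regions found in Gel replicate 1, the diluted Gel replicate 2 recovered 52.6% and CuNZ@Gel replicate 2 recovered 45.0%, and over both CuNZ@Gel libraries and both directions the differences were 6.55 to 7.68 percentage points, over the limit of 3, which argues against one factor as the whole cause but leaves open handling that libraries of a group may share. A lower yield of the immunoprecipitation and less acetylation in the cells cannot be told apart without a spike-in: at the strongest 20% of shared regions the larger CuNZ@Gel median height was 0.763 of the smaller Gel one, which either may give, and a change brought by the treatment stays open beside them.

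The strongest Gel-only regions may partly reflect local background. The median local background of the 20 highest was 1.153 times that of their library, against 1.0 over all Gel-only regions. This lay between the limits of 1.1 and 1.5 set beforehand, so the median leaves the set undecided. The 20 were mixed, however, and a median describes them poorly. The highest lay on chromosome 9 from 123724523 to 123724833, where the local background was 18.4 and 12.7 times that of the library in Gel replicates 1 and 2. On chromosome 8, it was 8.76 and 10.2 times in the region from 20697432, and 7.93 and 7.56 times in that from 20692811. It was 1.0 times in both libraries for the regions on chromosome 14 from 54770225 and on chromosome 8 from 38754922. Another, on chromosome 8 from 124160120 to 124160373, had a local background of 1.0 times and 59 and 60 summit fragments in Gel, with no CuNZ@Gel peak. No biological explanation was tested for these regions.

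A hypothesis that Gel-only regions lie next to one another found nothing. The nearest neighbour was also Gel-only for 27.11% of them, against 27.13% on average and 25.46 to 28.62% over 1000 permutations within groups of like strength (one-sided permutation p = 0.5145).

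A last hypothesis was that summit heights in regions with peaks in all 4 libraries may differ between the groups by unequal amounts. The SD over regions of the log2 height difference was 0.3133 between the groups, against 0.1961 and 0.1936 in the other splits, and the median difference, CuNZ@Gel minus Gel, was -0.269. Heights are recovered from authors' values of separately called lists. At the strongest 20% of regions the median log2 height was 4.71 in both Gel libraries and 4.28 and 4.32 in CuNZ@Gel. A trend with strength may thus be part of this spread. Only regions called in all 4 libraries enter, and the lowest −log10 p was 3.37 and 3.41 in the CuNZ@Gel lists against 3.12 in both Gel lists. The CuNZ@Gel libraries were also shallower. Weak regions that fell most in CuNZ@Gel can therefore be missing, which may narrow the difference at weak regions. Limma on log2 heights, run after the width fits, gave 6149 lower and 199 higher of 21909, and 800 lower and 491 higher after centring each library. Without any 1 library the calls ranged from 2349 to 6783 as recovered and from 95 to 2771 after centring, with the spread taken from 1 pair. The division into lower and higher thus depends on the scaling, and it describes only regions called in all 4 libraries. Correlations of log2 heights over these regions were 0.963 within Gel and 0.926 within CuNZ@Gel, against 0.909 to 0.922 across groups.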
